A study of Mus musculus with 10 samples.

How the data were processed

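Whole-transcript Affymetrix expression arrays measured total RNA from mouse dentate gyri at 5 ages, with 2 arrays per age. Per the labels' protocols, both gyri were cut out with a hypodermic needle tip, dissociated with tweezers and a pipette in the presence of DNase, and the nucleic acid was fragmented and biotinylated with a terminal labelling kit. The deposited values are taken here as log2 expression per probe set, because they run continuously from about 2.50 to 15.0 with like quartiles on every array; neither the log base nor the software for background correction, summarization and normalization is given in the sources used here. Per the submitters' processing notes the genome build was mm10, with no version of any tool. The array medians lie between 8.27 and 8.31, but the whole distributions are not identical.

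The deposited table holds 25254 probe sets. The platform annotation gave 1 gene for 21496 of them, several genes for 1565 and none for 2193. Symbols were checked through gene numbers against a RefSeq gene table of assembly GRCm38.p6, from which the coordinates come; 0 symbols changed, and 81 single-gene probe sets had a gene number that the table lacks. Probe sets with several genes or none were left out of the gene tests. For the 938 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 19752 genes, with no filter on dim genes. Arrays were taken by age and replicate number from the sample titles. Genes of olfactory, vomeronasal and trace amine receptors, 1203 in all, served as a reference for dim signal, since few of them are thought to be expressed in brain; the 95th percentile of their levels averaged 7.01 log2 units over the arrays. Genes whose mean lies under it are called dim.

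Every test used limma 3.58.1 in R 4.3.3 with default empirical Bayes settings, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The trend over age was the coefficient of age in weeks as a number (8 residual degrees of freedom) and is given as the log2 change over the 8 weeks of the series. Age as a factor (5 residual degrees of freedom) gave a moderated F-test over any ages, the comparison of 12 with 4 weeks, and the 4 successive steps. Errors of changes are standard errors; errors of group means are SDs over 2 arrays, and the small number of arrays limits the precision of both. The labels do not say whether the 2 arrays of an age came from separate animals or pools, so p-values measure the spread between these arrays, which may be partly technical. No scan date or batch was given.

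The tests, the gene lists, the named genes and the alternative fits were chosen before the data were examined. The 38 lists cover cell types of the dentate gyrus, cell types of neighbouring tissue and pathways; 36 of them had at least 5 measured genes. They were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists, and again with camera at a correlation estimated from the data and with fry. The genes named are the 12 largest rises and 12 largest falls of the trend, the 5 largest in each direction between 12 and 4 weeks, the 3 largest in each direction of each step (or the 3 of smallest p in each direction where none passed), and the 5 genes of smallest p in the F-test that did not pass the trend. For every list its first 3 measured members are named, and up to 4 further called members of largest change where the list passed. Predicted genes were counted but not named. Where a named gene had several probe sets, their directions over age were compared. Of the named genes 10 had several, and 0 of these had probe sets of opposite direction. The size of the change could differ, as for Acer2 and Disp1 below. Genes outside these rules were chosen after their values were seen, and the text says so.

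On simulated data made from the real means and spread of 19752 genes, the trend recovered 58.2% of genes changed by 0.4 log2 units over the series, 95.5% of those changed by 0.8 and 100% of those changed by 1.2. The comparison of 12 with 4 weeks recovered 16.4%, 80.6% and 93.9% at the same sizes, and that of 12 with 10 weeks 37.3%, 86.6% and 98.5%. Both comparisons were simulated in the same way, so the difference between them comes from the random draw. Each draw held 67, 67 and 66 changed genes of these sizes. Recovery after adjustment depends on how many genes change, so these rates do not show that a comparison with 0 calls had no change. With no change simulated, 2 genes passed the trend and 0 lists were called. The noise was drawn independently for each gene, so the simulation does not measure false list calls from genes that vary together. The alternatives were the replicate number as a block, quantile normalization, median centring, leaving out the dimmest 30% of genes, trended and robust variances, array weights, the mean over a gene's probe sets, the choroid plexus list as a covariate, log2 of age, a linear contrast over the age means, a minimum change of 1.5-fold, both other set tests, and leaving out each array in turn. Leaving out both arrays that stand apart from the rest, and leaving out the 12-week arrays, were added after the data had been seen. With age as a factor, leaving out either array of an age outside a comparison of 2 ages gives that comparison the same fit. Figures were drawn with matplotlib 3.10.9.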

Results

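Gene expression was measured in the dentate gyrus, the hippocampal region in which granule neurons continue to be born after birth, of mice of a strain that the labels write C56BL/6J. The 10 arrays fell into 5 ages, 4, 6, 8, 10 and 12 weeks, with 2 arrays each. The series title concerns biomarkers of neural progenitor cells, and the comparisons below ask which genes and cell type markers changed over these ages. Pearson correlations across genes between arrays ranged from 0.994 to 0.998. The array of 8 weeks replicate 1 had the lowest mean correlation with the others, 0.9949, and the narrowest distribution (SD 2.12). The array of 6 weeks replicate 1 had a level of 13.77 log2 units for Ttr, the transthyretin gene that is abundant in choroid plexus, against 8.87 to 10.15 on the others. The labels gave the sex as female. Xist, the transcript of the inactive X chromosome, lay between 5.41 and 6.02 on all 10 arrays, at or under the 13.2nd percentile of genes, and the Y-linked genes Eif2s3y, Kdm5d and Uty averaged 8.97, 9.06 and 9.23.

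Genes of newborn neurons and their precursors fell between 4 and 12 weeks. Cd24a, a surface glycoprotein gene of immature neurons, fell from 10.28 ± 0.04 at 4 weeks to 8.38 ± 0.03 at 12 weeks (log2, SD, n = 2). Its fitted change over the series was −1.83 ± 0.15 (SE), or 3.55-fold lower. Igfbpl1, expressed in intermediate progenitors, fell 2.55-fold (−1.35 ± 0.10, adjusted p = 8.4e-05). Dcx, which encodes the microtubule-binding protein doublecortin of migrating and immature neurons, fell 2.53-fold (−1.34 ± 0.13, adjusted p = 0.00043), from 10.41 ± 0.04 to 9.03 ± 0.07 (SD, n = 2). Eomes, the transcription factor Tbr2 of intermediate progenitors, fell 2.20-fold (−1.14 ± 0.10, adjusted p = 0.00030). In mm10 coordinates these protein-coding genes lie on chromosome 10 at 43579169 to 43584265 (Cd24a), on chromosome 4 at 45809507 to 45826827 (Igfbpl1), on the X chromosome at 143855842 to 143933396 (Dcx) and on chromosome 9 at 118478186 to 118486132 (Eomes).

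The other large falls were those of Sema3c, a secreted axon guidance cue (−1.21 ± 0.09), Tnc, the matrix glycoprotein tenascin C (−1.19 ± 0.20), and Enpp6, a choline phosphodiesterase of newly forming oligodendrocytes (−1.18 ± 0.15). Next came Dpysl3 (−1.08 ± 0.11), Sfrp1, a secreted Wnt modulator (−1.01 ± 0.12), and Bmp4, a secreted growth factor (−0.96 ± 0.08). They were followed by Zfp57, a zinc finger protein that maintains imprints (−0.94 ± 0.09), and Dpysl5 (−0.91 ± 0.06, with the lowest adjusted p of the series, 3.8e-05). Dpysl3 and Dpysl5 encode collapsin response mediator proteins of growing neurites. The largest rises were smaller. Acer2, an alkaline ceramidase, rose 1.74-fold (0.80 ± 0.15, adjusted p = 0.034). Its mean stood between 7.60 and 7.88 up to 10 weeks and at 8.53 ± 0.03 (SD, n = 2) at 12 weeks. The other probe set of Acer2, with a mean of 6.82 under the dim reference, had a change of 0.03. Rsrp1 rose by 0.65 ± 0.12, and Acvr1c, an activin-type receptor, by 0.57 ± 0.11. The rise of Ntng1, the synaptic adhesion protein netrin G1, was 0.55 ± 0.09. That of Il33, an interleukin found in the nucleus of oligodendrocytes and astrocytes, was 0.55 ± 0.09. Disp1 rose by 0.45 ± 0.07, Ano3 by 0.44 ± 0.07, Arsj by 0.42 ± 0.08, Krt9 by 0.42 ± 0.08 and Fmn1 by 0.41 ± 0.08. The other probe sets of Disp1 (mean 7.60), Ano3 and Ntng1 had changes of 0.10, 0.36 and 0.34. Mmp8 (0.65 ± 0.13) and Il2 (0.49 ± 0.07) also passed but are dim, with means under the 95th percentile of the receptor genes.

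In all, 162 of 19752 genes had a linear trend at an adjusted p under 0.05 in limma, 29 higher and 133 lower with age, and 2309 had an unadjusted p under 0.05. With quantile normalization the split was 65 higher and 131 lower. The median change was −0.48 for the falling and 0.39 for the rising genes, and the age means fell at every step for 90 of the 133 and rose at every step for 21 of the 29. The count was 35 without 4 weeks replicate 1, 54 without 4 weeks replicate 2, 91 without 12 weeks replicate 1, 104 without 12 weeks replicate 2, 102 without 10 weeks replicate 2, 279 without 8 weeks replicate 1, and 51 without the 12-week arrays. Of the 12 falling genes named, 11 passed in every alternative fit (Tnc did not pass without either 4-week array), and of the 12 rising genes 0 did. Of the trend genes named by the rules set in advance, 29 lost the call in at least 1 alternative. The number was 12 of 22 for Olig1, 12 of 21 for Mmp8, 10 of 22 for Tdo2, 9 for Fmn1, Id3 and Ugt8a, 8 for Acer2, Krt9 and Rsrp1, and 7 for Arsj. It was 6 for Acvr1c, Slc17a6 and Tpx2, 5 for Adamts4 and Ano3, and 4 for Disp1, Nes, Ntng1 and Top2a. It was 3 for Lpar1, Mcm7 and Olig2, 2 for Cnp, Il33 and Tnc, and 1 for Gpr17, Hmgb2, Il2 and Mki67. Leaving out 4 weeks replicate 1 ended the calls of all 29 but Gpr17, Hmgb2 and Il2, which were lost without the 12-week arrays.

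**Figure D1:**
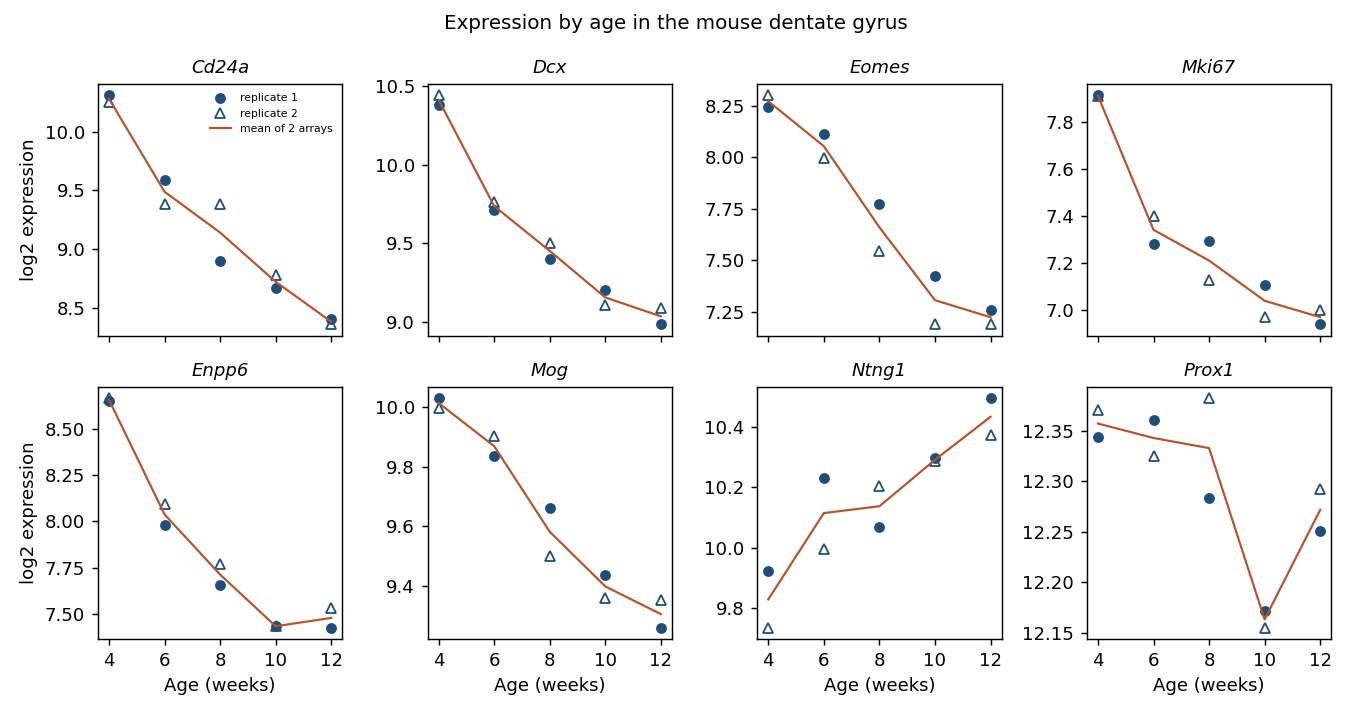
Log2 expression (vertical axes, with a separate range in each panel) against age in weeks for 8 genes, with a filled circle for replicate 1, an open triangle for replicate 2 and a line through the means of 2 arrays. Cd24a, Dcx, Eomes, Mki67, Enpp6 and Mog are lower at 12 than at 4 weeks and Ntng1 is higher, while Prox1, with a fitted change of −0.14 ± 0.07 (SE), did not pass the trend test.

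Among the fixed lists, neuroblasts and immature neurons had the lowest p (camera adjusted p = 2.3e-24). Of its 29 measured genes 27 had negative changes, with a median of −0.35; 8 fell in the test over all genes and 19 adjusted over the list alone, and 0 rose. Besides Cd24a, Dcx, Dpysl3 and Dpysl5, Sox4, a transcription factor of differentiating neurons, fell by 0.74 on the log2 scale (adjusted p = 0.0013). Neurod1 (−0.41 ± 0.12) and Neurod2 (0.03 ± 0.06), transcription factors that are also expressed in mature granule cells, did not pass over all genes. The cell cycle list fell as well (49 genes, adjusted p = 7.8e-18), with 8 genes past the threshold over all genes and 22 adjusted over the list alone. Mki67, the proliferation marker Ki-67, changed by −0.87 ± 0.12, Ccna2 by −0.87 ± 0.09, Top2a by −0.74 ± 0.13, Rrm2 by −0.58 ± 0.07, Tpx2 by −0.53 ± 0.09 and the replication helicase subunit Mcm7 by −0.42 ± 0.07; Cdk1 had a change of −0.32 ± 0.10 that did not pass over all genes.

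Of the 19 genes of intermediate progenitors, 4 fell over all genes and 7 adjusted over the list alone (camera adjusted p = 1.0e-08): Igfbpl1, Eomes, Slc17a6, a vesicular glutamate transporter (−0.72 ± 0.13), and Sstr2, a somatostatin receptor (−0.69 ± 0.09). Neurog2 (−0.23 ± 0.12) and Insm1 (−0.24 ± 0.08) did not pass over all genes. The intermediate progenitor genes had a median change of −0.12 and a mean of −0.32. Radial glia-like stem cell genes had a like median, −0.12, and a smaller mean change, −0.14 (25 genes, camera adjusted p = 2.0e-05). There 3 fell, Nes, the intermediate filament nestin (−0.52 ± 0.08), Lpar1 (−0.49 ± 0.08) and Id3 (−0.40 ± 0.08); the count adjusted over the list alone was 4, with Hopx (−0.21 ± 0.06) added, and Gfap had a change of −0.12 ± 0.07 that did not pass. The calls of these 4 lists held with an estimated correlation, at adjusted p = 0.025 for neuroblasts, 0.0012 for the cell cycle, 0.029 for intermediate progenitors and 0.042 for radial glia-like cells.

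Mature granule cell genes were called as higher (25 genes, median 0.05, adjusted p = 0.019), but with an estimated correlation the adjusted p was 0.69. Over all genes Ntng1 rose and Tdo2, a tryptophan dioxygenase of these cells, fell (−0.44 ± 0.08); adjusted over the list alone the counts were 5 higher and 2 lower. Prox1, the transcription factor of granule cell identity, had a change of −0.14 ± 0.07, Calb1 of −0.05 ± 0.08 and C1ql2 of 0.19 ± 0.06, none of them past the threshold over all genes. The list was not called without 4 weeks replicate 1 (adjusted p = 0.051), without 12 weeks replicate 1 (0.21) or without the 12-week arrays (0.38).

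The oligodendrocyte lineage also had lower levels at the older ages. Of 17 precursor genes 6 fell over all genes and 10 adjusted over the list alone (camera adjusted p = 2.6e-12, and 0.0012 with an estimated correlation). The falls were led by Enpp6, Bmp4 and Gpr17 (−0.77 ± 0.09), genes known from precursors committed to differentiate, and Olig2 (−0.50 ± 0.08) and Olig1 (−0.32 ± 0.06), transcription factors of the whole lineage, fell less; Pdgfra (−0.16 ± 0.08) and Cspg4 (−0.14 ± 0.07), surface markers of dividing precursors, did not pass. Among 29 genes of myelinating oligodendrocytes 9 fell and 1, Il33, rose, and adjusted over the list alone 13 fell and 2 rose (adjusted p = 5.0e-07, but 0.087 with an estimated correlation). Mog, a myelin surface glycoprotein, changed by −0.76 ± 0.07, Ugt8a, a galactolipid synthase, by −0.73 ± 0.14, Tspan2 by −0.72 ± 0.09, Mag by −0.72 ± 0.10, Cldn11 by −0.66 ± 0.08 and Cnp by −0.57 ± 0.09. Mbp, the myelin basic protein gene, changed by −0.27 ± 0.06 and did not pass over all genes (adjusted p = 0.055), but it did in 4 alternatives, among them the fit without 8 weeks replicate 1 (0.046). The calls of Olig1 and Ugt8a were lost without either 4-week array (adjusted p = 0.19 and 0.12 for Olig1, and 0.19 and 0.17 for Ugt8a).

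All 20 measured genes of cholesterol synthesis had negative changes, with a median of −0.19 (camera adjusted p = 5.8e-12, but 0.13 with an estimated correlation). None passed over all genes, and 10 did adjusted over the list alone; Hmgcs1, which makes the precursor of mevalonate, had a change of −0.39 ± 0.10, Mvk of −0.13 ± 0.07 and Pmvk of −0.13 ± 0.07. In the list of the perineuronal net and matrix (20 genes, adjusted p = 1.2e-06, and 0.0058 with an estimated correlation) Tnc, the link protein gene Hapln1 (−0.61 ± 0.06) and the matrix protease gene Adamts4 (−0.50 ± 0.09) fell over all genes, and 9 fell adjusted over the list alone. The proteoglycan genes Acan (−0.21 ± 0.06), Bcan (−0.26 ± 0.08) and Ncan (−0.25 ± 0.07) did not pass over all genes. This list shares 2 genes with the precursor list and 2 with the myelin list. Among 23 genes of DNA methylation and chromatin (adjusted p = 0.00015, but 0.051 with an estimated correlation), Tet1, which oxidises 5-methylcytosine (−0.55 ± 0.07), and Hmgb2, a chromatin protein of dividing cells (−0.55 ± 0.06), fell, and 5 fell adjusted over the list alone. Dnmt1 (−0.19 ± 0.07), Dnmt3a (−0.33 ± 0.09) and Dnmt3b (−0.09 ± 0.07) did not pass over all genes.

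Oxidative phosphorylation was called as lower with small changes (35 genes, median −0.05, adjusted p = 0.0021, but 0.16 with an estimated correlation), and heat shock and stress genes as higher (20 genes, median 0.04, adjusted p = 0.034, but 0.56 with an estimated correlation). None of their members passed over all genes or adjusted over the list alone: Ndufa1 had a change of −0.05 ± 0.08, Ndufa2 of 0.03 ± 0.06, Ndufa4 of 0.00 ± 0.07, Hspa1a of 0.45 ± 0.14, Hspa5 of −0.05 ± 0.10 and Hspa8 of −0.02 ± 0.05. Without the 12-week arrays oxidative phosphorylation was not called (adjusted p = 0.073), and heat shock was not called and its test pointed lower (0.75). Heat shock was also not called without either 12-week array (0.33 and 0.17) or 6 weeks replicate 2 (0.051), or on log2 of age (0.11). In all, 12 of 36 lists were called, 2 higher and 10 lower, and 6 of them with an estimated correlation.

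**Figure D2:**
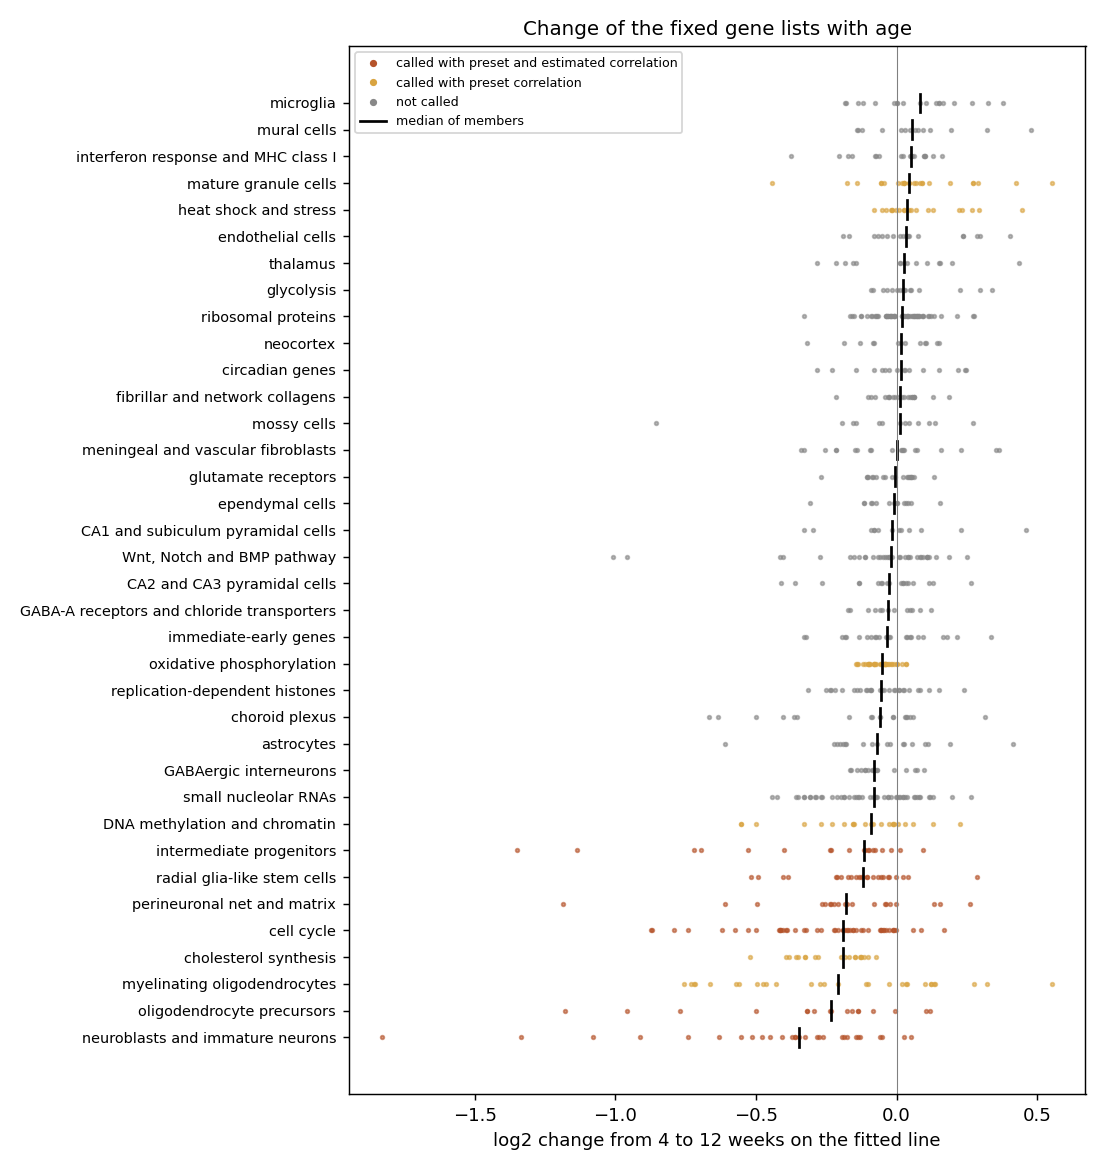
Fitted log2 change from 4 to 12 weeks (horizontal axis) for each measured gene (points) of the 36 lists tested (vertical axis), with the median of each list as a black bar and the lists ordered by it. Lists called by camera with both the preset and the estimated correlation are red, lists called with the preset correlation alone are yellow, and lists not called are grey; the median is lowest for neuroblasts and immature neurons, at −0.35.

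The lists of other cells were not called over age. They were astrocytes (adjusted p = 0.052), microglia (0.22), endothelial cells (0.23), mural cells (0.23), meningeal fibroblasts (0.69), choroid plexus (0.43), ependyma (0.63), pyramidal cells of CA1 (0.92) and of CA2 and CA3 (0.58), mossy cells (0.63), GABAergic interneurons (0.072), thalamus (0.36) and neocortex (0.69). The astrocyte list was called as lower in 7 of 24 alternatives. These were fry (adjusted p = 0.022), median centring (0.040), array weights (0.048), and the fits without 4 weeks replicate 1 (0.039), 4 weeks replicate 2 (0.029), 8 weeks replicate 1 (0.0496) or 10 weeks replicate 2 (0.033). Endothelial cells were called as higher without 6 weeks replicate 1 (0.048) or 10 weeks replicate 1 (0.045). Microglia were called as higher without 4 weeks replicate 1 (0.044) and as lower without the 12-week arrays (0.019). Choroid plexus was called as lower without 4 weeks replicate 1 (0.039), and interneurons without 4 weeks replicate 2 (0.0092) or 10 weeks replicate 1 (0.023). For mossy cells and neocortex the test pointed lower while the median was above 0, at 0.01 and 0.02. In these lists Hapln1 of the astrocytes and, chosen after their values were seen, Cacng5 of CA2 and CA3 (−0.41) and Gal, the galanin gene in the mossy cell list (−0.86), fell over all genes. The microglial genes Cx3cr1 (−0.14 ± 0.06), P2ry12 (−0.18 ± 0.08) and Tmem119 (0.16 ± 0.08) and the astrocyte genes Aqp4 (−0.20 ± 0.10), Gja1 (−0.18 ± 0.05) and Gjb6 (0.10 ± 0.10) did not pass. Nor did Flt1 (0.40 ± 0.12), Cldn5 (0.24 ± 0.13) and Kdr (−0.19 ± 0.13) of the endothelium. The pericyte and muscle genes Pdgfrb (−0.14 ± 0.09), Rgs5 (−0.05 ± 0.09) and Abcc9 (0.10 ± 0.08) did not pass. The same held for Gad1 (−0.08 ± 0.05), Gad2 (−0.17 ± 0.07) and the GABA transporter gene Slc32a1 (−0.08 ± 0.06) of the interneurons.

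Lists of bordering tissue and of mossy cells of the hilus had members with no call. In the choroid plexus list Folr1 had a change of −0.01 ± 0.26 and Kl of 0.31 ± 0.19; Kl passed without 6 weeks replicate 1 (adjusted p = 0.020) and without both arrays that stood apart (0.016). The ependymal genes Foxj1 (0.00 ± 0.08), Tmem212 (−0.09 ± 0.15) and Ccdc153 (0.15 ± 0.13) did not pass. Nor did Wfs1 (−0.30 ± 0.14), Fibcd1 (−0.08 ± 0.12) and Pou3f1 (−0.07 ± 0.09) of CA1. Values for CA2 and CA3 were 0.02 ± 0.07 for the kainate receptor gene Grik4, 0.13 ± 0.07 for Cpne4 and 0.06 ± 0.08 for Bok. Mossy cell genes had changes of −0.15 ± 0.15 (Calb2, calretinin), 0.01 ± 0.09 (Drd2, a dopamine receptor) and −0.16 ± 0.10 (Calcrl). Thalamic genes had −0.21 ± 0.09 (Tcf7l2), −0.28 ± 0.13 (Prkcd) and 0.01 ± 0.11 (Lef1). Neocortical transcription factor genes had −0.19 ± 0.05 (Tbr1), −0.08 ± 0.06 (Rorb) and −0.13 ± 0.05 (Cux1). On all arrays none of these 20 genes passed over all genes.

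The comparison of 12 with 4 weeks used the ends of the same series, so its calls are not independent of the trend. Lcn2, which encodes lipocalin 2, a secreted iron-siderophore-binding protein of the acute-phase response (chromosome 2, 32384637 to 32387739), was higher at 12 weeks by 3.37 ± 0.32 (SE, adjusted p = 0.0029), with 10.05 ± 0.52 at 12 weeks and 6.68 ± 0.02 at 4 weeks (SD, n = 2). At 4 weeks it lay at 6.70 and 6.66, under the 95th percentile of the receptor genes on the same arrays (6.90 and 6.97), so the difference may be understated. Ch25h, cholesterol 25-hydroxylase, rose by 1.10 ± 0.12, Ppbp, a platelet chemokine gene, by 0.93 ± 0.14, Acer2 by 0.93 ± 0.11 and Fxyd5 by 0.79 ± 0.10; Ch25h and Ppbp are dim. The largest falls were those of Cd24a (−1.90 ± 0.14), Igfbpl1 (−1.40 ± 0.09), Dcx (−1.38 ± 0.07), Sema3c (−1.23 ± 0.09) and Enpp6 (−1.17 ± 0.07). Between these ages 102 genes passed in limma, 25 higher and 77 lower; 76 of them also had a trend, all 76 in the same direction. With quantile normalization the split was 54 higher and 87 lower. The count was 13 without 4 weeks replicate 1, 14 without 4 weeks replicate 2, 16 without 12 weeks replicate 1, 21 without 12 weeks replicate 2, 52 without either 10-week array and 188 without either 8-week array. Lcn2 itself did not pass without 4 weeks replicate 1 (adjusted p = 0.053) or replicate 2 (0.055). Ch25h did not pass without 4 weeks replicate 1 (0.093), 12 weeks replicate 1 (0.094) or 12 weeks replicate 2 (0.069). Acer2 did not pass without 4 weeks replicate 2 (0.088), 12 weeks replicate 1 (0.094) or 12 weeks replicate 2 (0.094). Fxyd5 did not pass without any 1 array of 4 or 12 weeks (0.11 to 0.18), and Ppbp without any 1 array of 4, 10 or 12 weeks (0.069 to 0.21).

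Between 12 and 4 weeks camera called 18 lists, 11 lower and 7 higher, and 5 of them held with an estimated correlation: neuroblasts (adjusted p = 0.016), cell cycle (0.010), oligodendrocyte precursors (0.010), perineuronal net and matrix (0.022) and DNA methylation and chromatin (0.042). Of the neuroblast genes 8 fell over all genes and 20 adjusted over the list alone, and of the cell cycle genes 6 and 21. Intermediate progenitors (0.060 with an estimated correlation), radial glia-like cells (0.23), myelinating oligodendrocytes (0.25), cholesterol synthesis (0.25), oxidative phosphorylation (0.22) and GABAergic interneurons (0.47) were called as lower with the preset correlation alone. The interneurons were also not called without 4 weeks replicate 1 (0.54), 12 weeks replicate 1 (0.084) or 12 weeks replicate 2 (0.083), with quantile normalization (0.060) or without the dimmest genes (0.079). The lists called as higher were endothelial cells, microglia, mural cells, meningeal fibroblasts, glycolysis, mature granule cells and heat shock, and none held with an estimated correlation, where the adjusted p was 0.40, 0.47, 0.47, 0.74, 0.40, 0.47 and 0.27. In the first 5 of these, 0 genes passed over all genes; adjusted over the list alone 3 endothelial, 3 microglial, 2 fibroblast and 3 glycolysis genes were higher, 1 microglial gene was lower, and 0 mural genes passed. Without 12 weeks replicate 2 the meningeal list pointed lower, with a median of −0.07, and the endothelial, mural and glycolysis lists were not called (adjusted p = 0.16, 0.19 and 0.070). Microglia were not called without 12 weeks replicate 1 (0.84), and mural cells and meningeal fibroblasts were not called without 4 weeks replicate 1 (0.085 and 0.087).

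The test over any ages asked for changes that need not be linear. It called 33 genes, of which 28 also had a trend, and 1672 had an unadjusted p under 0.05. The 5 that did not pass the trend were Lcn2 (adjusted p = 0.016), Ch25h (0.028, dim), Trpc5os (0.042, dim), Fxyd5 (0.042) and Xdh, xanthine dehydrogenase (0.042). Lcn2 stood at 6.70 and 6.66 on the arrays of 4 weeks, 8.54 and 7.47 at 6 weeks, 7.05 and 6.84 at 8 weeks, 7.09 and 7.06 at 10 weeks, and 10.42 and 9.69 at 12 weeks. Fxyd5 averaged 9.46, 9.99, 9.74, 9.40 and 10.25 over the successive ages, and Xdh 7.08, 7.46, 7.60, 7.94 and 7.67. The count of 33 was between 5 and 10 without either array of 4, 10 or 12 weeks, 17 without 6 weeks replicate 1, 50 without 8 weeks replicate 2 and 3 without the 12-week arrays, and 13 with the replicate number as a block; Lcn2 was not called without any 1 array of 4, 10 or 12 weeks. The any-age call was lost in 7 of 20 alternatives for Lcn2, 8 of 19 for Ch25h, 13 of 19 for Trpc5os, 11 of 20 for Fxyd5 and 11 of 20 for Xdh. Ch25h was lost without the same arrays as Lcn2. Fxyd5 and Xdh were lost without any 1 array of 4, 6 or 12 weeks and without 10 weeks replicate 1, and Xdh also without 10 weeks replicate 2. Trpc5os was lost without any 1 array but 8 weeks replicate 2.

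**Figure D3:**
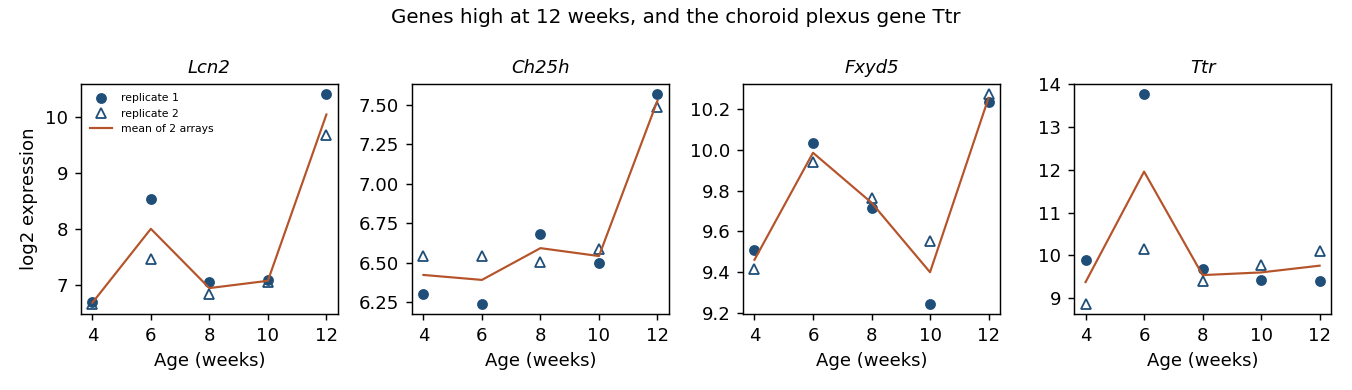
Log2 expression (vertical axes, with a separate range in each panel) against age in weeks for Lcn2, Ch25h, Fxyd5 and the choroid plexus gene Ttr, with a filled circle for replicate 1, an open triangle for replicate 2 and a line through the means of 2 arrays. Lcn2 lies at 10.42 and 9.69 on the 12-week arrays, and Ttr at 13.77 on the array of 6 weeks replicate 1.

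The successive steps were compared next. From 4 to 6 weeks the smallest p of falling genes belonged to Dcx (−0.68 ± 0.07), Enpp6 (−0.62 ± 0.07) and Dpysl3 (−0.55 ± 0.07), and of rising genes to Apod, apolipoprotein D (0.54 ± 0.09), Mgp, matrix Gla protein (0.57 ± 0.10), and Penk, proenkephalin (0.46 ± 0.08). No gene passed, and the lowest adjusted p was 0.10. In the step from 6 to 8 weeks these genes were Trpc5os (0.75 ± 0.08), Defb40 (0.43 ± 0.07) and Asb17 (0.38 ± 0.06), all dim, and Mir181b-1 (−0.48 ± 0.09, dim), P2ry10b (−0.52 ± 0.10, dim) and Mrpl42 (−0.41 ± 0.08), with a lowest adjusted p of 0.080. From 8 to 10 weeks they were Spink8, expressed in CA1 pyramidal cells (8.37 to 9.37), Dppa5a (0.47 ± 0.08, dim) and Dnaaf6 (0.48 ± 0.08, dim), and Vmn1r174 (−0.90 ± 0.15, dim), Gtf2ird1 (−0.32 ± 0.06) and Vmn1r199 (−0.43 ± 0.08, dim), with a lowest adjusted p of 0.87. From 10 to 12 weeks the rising genes were Lcn2 (2.98 ± 0.32), Fxyd5 (0.85 ± 0.10) and Ch25h (0.98 ± 0.12, dim). The falling genes were the clock gene Per3 (−0.40 ± 0.07), Alox12b (−0.53 ± 0.09) and Zc2hc1c (−0.46 ± 0.08, dim), and the lowest adjusted p was 0.11. In these 4 steps limma called 0 genes each, while 815, 1234, 946 and 1104 genes had an unadjusted p under 0.05. With trended and robust variances 11, 0, 0 and 7 genes were called. Without 6 weeks replicate 2 the first step called 10 genes and the second 7. The last step called 1 gene without 6 weeks replicate 1, without 6 weeks replicate 2 or without 12 weeks replicate 2. In the last step Lcn2 passed in 7 of 19 alternatives, Ch25h in 4 of 18 and Fxyd5 in 3 of 19. For Lcn2 these include the fits without either 6-week array, which are the same fit for this step and are not separate checks. That fit leaves out the spread between the 6-week arrays, where Lcn2 stood at 8.54 and 7.47. In the first step Dcx passed in 4 alternatives, Dpysl3 and Enpp6 in 3, and Apod and Penk in 1. Without 8 weeks replicate 2 the step from 6 to 8 weeks called 1079 genes, and it then rests on the array of 8 weeks replicate 1 that stood apart.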

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

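The tests of blood, of choroid plexus, of meninges, of white matter and of sex-linked genes were chosen after the results they bear on had been seen; those of the acute-phase response and of newly formed oligodendrocytes were set before their values were seen.

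Among the 3758 probe sets that the annotation ties to several genes or to none, and that entered no comparison, 6 had a trend with age in limma, 1 higher and 5 lower; 2 of them have several genes and 4 none. They were singled out because they lie outside the gene tests.

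Lcn2, Ch25h and Fxyd5 were higher at 12 than at 10 weeks by 2.98, 0.98 and 0.85 log2 units, although limma called 0 genes in this step (1104 at an unadjusted p under 0.05), and the largest mean differences above 0 among the fixed lists were those of the meningeal, microglial, immediate-early, endothelial, mural and heat shock lists (0.20, 0.18, 0.15, 0.14, 0.11 and 0.09). At 10 weeks Ch25h (6.50 and 6.59) lay under the 95th percentile of the receptor genes on the same arrays (7.07 and 7.08), and Lcn2 (7.09 and 7.06) lay near it. The differences of these genes may therefore be understated. The tables argue against blood as a whole. Its 4 adult globin probe sets, at 12.38 to 13.33 at 10 weeks, differed by −0.04 to 0.07. The median change of 16 blood cell genes (10 above the dim reference, 2 in a fixed list) was −0.0031 (95% interval −0.057 to 0.069). This interval, like that for choroid plexus below, came from 10000 resamplings of the genes of the list. It measures the spread among those genes and not the spread between the arrays of an age. However, S100a8 (0.61 ± 0.17) and Chil3 (0.61 ± 0.14), dim genes of white cells, were higher adjusted over the list alone. White cells by themselves therefore stay open. The tables also argue against choroid plexus as the whole cause. The median change of its 19 genes (12 above the dim reference) was −0.0963 (interval −0.143 to −0.011), with 15 lower and 4 higher. Of the brightest, Ttr averaged 9.60 and 9.76 at 10 and 12 weeks, Kl 9.09 and 9.10, and Slc13a4 8.19 and 8.74. Meninges as the whole cause are argued against by a fit with the mean of the meningeal list. There the changes of Lcn2, Ch25h and Fxyd5 were 3.02 ± 0.39, 1.03 ± 0.14 and 0.77 ± 0.11 (smallest lower 95% bound 0.5223). A part stays open. The meningeal list (median change of 20 genes 0.17) stood at −0.15 and 0.20 on the 12-week arrays. Centred per gene, it was highest on 6 weeks replicate 1 (0.31), which had the highest Lcn2 of the other ages. Its member Aldh1a2 (0.77 ± 0.14) came near the change of Fxyd5. An acute-phase response of the 12-week animals stays open: the 37 other genes of an endotoxin response list (28 above the dim reference, 1 in a fixed list) had a camera p of 0.0484 from 10 to 12 weeks (22 higher, 15 lower, 5 past the threshold over the list alone) and 3.03e-05 from 4 to 12 weeks (29 higher, 8 lower, 7 past the threshold over the list alone), but 0.508 and 0.193 with an estimated correlation. Of the 5 past the threshold from 10 to 12 weeks, Osmr, Vcam1, Sele and Cd14 were higher (0.45 to 0.55) and Plin4 was lower (−0.55 ± 0.12). Between 12 and 4 weeks 1 of the 37 genes passed over all genes. Ptx3 of this list fell over age (−0.51 ± 0.07, limma trend adjusted p = 0.0084). These genes were chosen after their values were seen. Age itself is the difference the design names and was not tested apart from such a response.

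The list of myelinating oligodendrocytes was called as lower with age (adjusted p = 5.0e-07, but 0.087 with an estimated correlation): 9 of 29 genes fell over all genes, Il33 rose, 11 had changes above 0, and Apod was higher at 12 than at 4 weeks (0.55, adjusted p = 0.036). Less white matter in the dissections of older animals would lower these markers alike, but 20 of the 29 departed from the mean change of the list (−0.21), 10 below and 10 above it, as did 10 of the 14 brightest from theirs, and the difference between Mbp and Mog changed by 0.48 ± 0.07. This was the last of 3 tests of white matter, and its limits were set after these values had been seen: the first, a rise of 1 or more of the genes, also counted against it (Il33), and the second, intervals of change above 0 (2 of 29), did not decide. Centring on the mean puts departures on both sides, so 10 below and 10 above do not by themselves count against white matter. Mog, Ugt8a, Tspan2, Mag and Cldn11 had like changes (−0.76 to −0.66), while 11 of the 29 had changes above 0. Markers that other cells also express would fall less, so the values count against white matter as the whole cause only as far as such signal is small, and a part stays open. Fewer newly formed oligodendrocytes at older ages may contribute: 17 of 19 marker genes of that stage (all above the dim reference, 1 in a fixed list) had negative changes (camera p = 2.03e-07, and 0.0046 with an estimated correlation), though over all genes only Bcas1 (−0.40) passed, and of the brightest Fyn and Nfasc averaged 11.48 and 11.32 at 4 weeks and 11.18 and 11.05 at 12 weeks while Ust averaged 11.08 and 11.21. Less white matter could lower these markers too, so their fall does not tell the explanations apart.

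Xist lay at or under the 13.21st percentile of genes on each of the 10 arrays, and Eif2s3y, Kdm5d and Uty lay above the 53rd. Animals of another sex than the label gives could have these levels. Probe sets that do not follow the transcripts they are named for could too: 0 arrays of the other label were at hand, and Sry, which is little expressed in brain, averaged 8.11, so this stays open. No biological explanation was tested.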

How the results depend on the processing

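Leaving out both arrays that stand apart, and leaving out the 12-week arrays, were chosen after seeing the data. The 162 genes with a trend kept their sign in every alternative fit, and 27 of them, all lower with age, passed in each of the fits, the minimum change of 1.5-fold left aside. The kept signs say little, since the 162 genes were chosen on these same arrays and every alternative fit used most of the arrays. Of 100 orders of the ages over the arrays, 1, the real one, gave as many genes as the real order. The highest of the others gave 0. A count of 162 is thus unlikely to arise by chance if the 10 arrays are independent, which the labels leave open. With 100 orders a share below 1 in 100 cannot be resolved. Counts moved by over 1.5 times as follows, for the trend (162), any ages (33), 12 against 4 weeks (102) and the steps from 4 to 6 and from 10 to 12 weeks (0 each). Without the dimmest genes they were 337, 69, 210, 3 and 3, with trended and robust variances 363, 158, 304, 11 and 7, and with array weights 417, 69, 261, 3 and 4. The choroid plexus covariate gave 18 genes for any ages, 63 for 12 against 4 weeks and 1 for 10 to 12 weeks. Quantile normalization gave 1 gene for 4 to 6 weeks and 2 for 10 to 12 weeks, where leaving out both arrays that stand apart also gave 2. Leaving out the 12-week arrays gave 51 trend genes and 3 for any ages, with fewer arrays. A minimum change of 1.5-fold, which can only lower a count, left 44 trend genes and 60 for 12 against 4 weeks. Other causes were not tested. The replicate number as a block gave 161 trend genes, 13 for any ages, 66 for 12 against 4 weeks and no change in the number of lists. Same-numbered arrays shared deviations above a correlation of 0.1 in 3 of 10 pairs of ages (range −0.335 to 0.160). No pairing common to the ages was seen over all genes, but an effect of the replicate number on part of the genes is not excluded. Leaving out each array in turn gave 35 to 279 trend genes, 5 to 50 for any ages, 13 to 188 for 12 against 4 weeks, 0 to 10 from 4 to 6 weeks, 0 to 1079 from 6 to 8 weeks, 0 to 0 from 8 to 10 weeks and 0 to 1 from 10 to 12 weeks, and 11 to 15 lists over age and 14 to 18 between 12 and 4 weeks; the lone array of an age is then assumed to vary like the others. With an estimated correlation 6 of 12 lists were called over age and 5 of 18 between 12 and 4 weeks, where fry called 8. A list's call turned direction, or appeared in the other direction, in 3 cases: meningeal fibroblasts between 12 and 4 weeks without 12 weeks replicate 2 (median −0.0695, against 0.2738 without 12 weeks replicate 1), and without the 12-week arrays microglia over age (−0.0774, called as lower) and heat shock over age (median 0.0171, test pointing lower). Over the named genes and all their alternatives, 3759 results kept their side of the threshold, 223 lost it, 42 gained it and 0 reversed. Over the lists 1537 kept it, 50 lost it and 30 gained it. Most of these results belong to genes or lists that were not called on all arrays, and those cannot lose a call. Set against the totals, 223 and 50 therefore understate how often a call was lost. Arrays give no depth, and near the dim reference of 7.01 log2 units a change may be understated: 3 of the falling and 5 of the rising trend genes lie under it.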

Other observations

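The test of curvature below was set before its values were seen, on a shape noted in the age means.

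Several groups fixed in advance were not called over age on all arrays. Glutamate receptor genes (21 measured, median −0.01) included Gria1 at 0.06 ± 0.05, Gria2 at 0.06 ± 0.07 and Gria3 at −0.04 ± 0.07 log2 units over the series, and GABA-A receptor and chloride transporter genes (13 measured, median −0.03) Gabra2 at 0.04 ± 0.10, Gabra3 at −0.06 ± 0.15 and Gabra4 at 0.08 ± 0.06. Neither list was called (camera adjusted p = 0.61 and 0.63), but glutamate receptors were called as lower without the 12-week arrays (0.027). The immediate-early genes (adjusted p = 0.86, but 0.00035 and lower without the 12-week arrays) had Fos at −0.03 ± 0.18, Fosb at 0.07 ± 0.14 and Junb at 0.04 ± 0.07; chosen after its value was seen, Ptgs2 of this list was higher at 12 than at 4 weeks by 0.48. Circadian genes (0.63) had Arntl at 0.04 ± 0.08, Clock at −0.05 ± 0.05 and Per1 at 0.03 ± 0.08.

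The Wnt, Notch and BMP list was not called (36 genes, adjusted p = 0.23), but Sfrp1, Bmp4 and Id3 of it fell over all genes and, adjusted over the list alone, 4 did; Wnt3 had a change of 0.08 ± 0.08, Wnt5a of −0.41 ± 0.12 and Wnt7a of −0.17 ± 0.08. Interferon response and MHC class I genes (0.86) had B2m at 0.10 ± 0.09, H2-Q4 at 0.10 ± 0.09 and Tap1 at 0.05 ± 0.07. The remaining lists, none of them called over age, were collagens (0.86; Col1a1 −0.09 ± 0.08, Col1a2 −0.21 ± 0.11, Col3a1 0.02 ± 0.10), glycolysis (0.18; Hk1 0.00 ± 0.05, Pfkm −0.03 ± 0.06, Pfkp 0.03 ± 0.07), ribosomal proteins (0.34; Rpl10 0.09 ± 0.06, Rpl10a −0.07 ± 0.07, Rpl10l −0.10 ± 0.18), small nucleolar RNAs (0.074; Snora16a 0.06 ± 0.22, Snora20 −0.08 ± 0.19, Snora21 0.00 ± 0.12) and replication-dependent histones (0.089; H1f1 −0.23 ± 0.07, H1f10 −0.11 ± 0.07, H1f2 0.08 ± 0.22). The small nucleolar RNA list had a median of −0.08, with 33 of 50 genes negative. It was called as lower in 7 of 24 alternatives: without 12 weeks replicate 1 (adjusted p = 0.00016), the 12-week arrays (0.013), 10 weeks replicate 2 (0.016), 4 weeks replicate 1 (0.039) or 8 weeks replicate 1 (0.0496), with median centring (0.037) and on log2 of age (0.046). The histones were called as lower in 3 alternatives: without 12 weeks replicate 1 (3.4e-05), without the 12-week arrays (0.0028) and on log2 of age (0.048). Ribosomal proteins were called as higher without 4 weeks replicate 2 (0.0058). Only 4 erythroid genes and 0 mitochondrially encoded genes were measured, so these lists were not tested; Alas2 had a change of −0.18 ± 0.13, Slc4a1 of 0.04 ± 0.10 and Bpgm of −0.15 ± 0.07.

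The fall of newborn-neuron genes may be steeper at the start of the interval. The mean change of the 29 neuroblast genes was −0.22 from 4 to 6 weeks, −0.09 from 6 to 8, −0.11 from 8 to 10 and −0.02 from 10 to 12 weeks. A quadratic term of age was positive for 23 of the 29 genes (camera p = 3.77e-12, and an adjusted p over 6 lists of 0.037 with an estimated correlation), as a fall that slows would give. No single gene passed for that term in limma, where 1518 genes had an unadjusted p under 0.05. Of 5 other falling lists tested the same way, 4 passed with the preset correlation: intermediate progenitors (adjusted p = 0.039), cell cycle (0.039), myelinating oligodendrocytes (0.039) and cholesterol synthesis (0.013). With an estimated correlation the adjusted p of the 5 lay between 0.32 and 0.37, so the shape is not shown to be particular to neuroblasts. The shape is a hypothesis, found and tested on the same arrays.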
